A study of Homo sapiens with 8 samples.

How the data were processed

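MicroRNAs (miRNAs), short RNAs that repress the translation and stability of messenger RNAs, were profiled in cultured dermal fibroblasts from foot skin biopsies of diabetic and non-diabetic people. Per the labels' protocols, the epidermis was removed, the minced dermis was placed in culture until fibroblasts grew out, and RNA of early passages was isolated with a column kit. Per the labels, 100 ng of total RNA entered each nCounter assay, in which colour-coded probes are hybridised to individual RNA molecules and counted. Group membership came from the sample titles, which name 4 diabetic and 4 non-diabetic samples. The numbers in the titles are not shared between the groups and were used neither for pairing nor as names, and replicates are numbered 1 to 4 within each group in the order of deposit. Separate sample numbers are given, but the labels do not state that each sample came from a different person, and p-values measure the spread between these samples.

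The authors deposited a table of raw counts per probe, in whole numbers, for 800 miRNA probes, 5 reference mRNA probes (ACTB, B2M, GAPDH, RPL19 and RPLP0), 6 positive controls, 6 negative controls and 5 spike-in probes. The normalized table deposited by the authors and the series matrix hold a background-subtracted signal, identical in 6400 of 6400 miRNA values. Per the submitters' design text, values were analysed in nSolver 2.0 and normalized to control genes of the assay. Setting the deposited signal against the deposited counts gave its construction: the mean plus 2 SD of the negative controls was subtracted per sample, values under 1 were set to 1, and all values, those set to 1 included, were multiplied by one factor per sample (0.504 to 2.10), with a floor of 1 again. All 805 of 805 miRNA and reference mRNA values in each sample were rebuilt within 0.02 or, for the larger values, within a small fixed fraction of the value. The authors' deposited fold change table holds a score per probe, a signed ratio of the group geometric means of that signal, negative where the diabetic group is lower, with no p-values. That construction was met within 0.02 for 805 of 805 probes. The genome build and the probe annotation version are not given in the sources used here, and no coordinates are printed. The 5 reference mRNA probes were matched by accession to the RefSeq gene table of the human reference assembly (5 of 5).

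The raw counts were tested. Design, alternatives, miRNA lists and the rule for named miRNAs were fixed before the data were examined. The planned scaling was the authors' factor per sample, taken as normalized over raw value, with the geometric mean of the 5 reference mRNA probes as the fallback. Because background subtraction leaves no single ratio per sample, the fallback became the main scaling, and the alternative of that name, fixed beforehand, is identical to it. A miRNA was tested if its count exceeded the background, the mean plus 2 SD of the 6 negative controls of the same sample, in at least 4 samples, which held for 65 miRNAs. Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust dispersion and fit) with Benjamini-Hochberg adjustment at 0.05. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The number of miRNAs above background and the ratio of summed miRNA counts to the reference mRNAs were compared with two-sided exact permutation tests, whose smallest possible p with 4 against 4 samples is 0.0286. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

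Named miRNAs were those past the threshold, filled up to 6 in each direction by the smallest unadjusted p and then given as values. The rule also took the 10 with the highest mean scaled count, the 2 tested members of each list with the smallest p, the 5 tested miRNAs with the largest deposited fold change, and the reference mRNA probes. This gave 33 miRNAs. The 19 lists covered miRNA families, genomic clusters, functional groups from the literature, and markers of other cells a dermal culture could hold.

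Alternatives changed one choice at a time, except that the deposited signal and the mean-subtracted counts were tested with limma, which changed the test as well, and that DESeq2 with its own size factors changed scaling and test together. They covered TMM, positive control, top 100 miRNA and total miRNA scaling, the background rule and low-count filter, the deposited signal on a log2 scale with a pseudocount of 1 or 20 in limma, subtraction of the mean negative control, the cartridge lane as a block (lanes 1 to 6 against 7 to 12) or as a covariate, each sample left out, DESeq2 1.42.0, limma-voom and non-robust estimation. TMM takes its factors from the tested miRNAs themselves and holds their average change near 0. The lane numbers are those in the column names of the deposited tables.

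Total counts, controls included, ran from 96353 to 207235 per sample. The biological coefficient of variation was 0.58 under reference mRNA scaling and 0.32 under TMM scaling, and the median 95% interval of a fold change ran from 0.42 to 2.64 and from 0.66 to 1.46. The test was run on simulated counts for the 65 miRNAs with 20 changed per run over 50 runs. It recovered 5.0% of 2-fold, 36.1% of 3-fold, 69.5% of 4-fold and 98.8% of 8-fold changes under reference mRNA scaling, against 63.1%, 94.9%, 98.9% and 99.3% under TMM scaling. At 2-fold, 10.7% and 4.97% of the calls were false. The simulated miRNAs varied independently of each other. In the data the estimated correlation within tested lists was 0.554 to 0.948 under reference mRNA scaling, and -0.185 to 0.455 under TMM scaling. The recovery rates therefore need not hold for these samples, above all under reference mRNA scaling. All 12 same-group sample pairs differed by more than sampling noise (lowest chi-square per degree of freedom 43.0), and no sample was a copy of another.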

Results

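Dermal fibroblasts produce and remodel the collagen-rich matrix of the skin. Their miRNAs were counted in primary cultures from foot skin of 4 diabetic and 4 non-diabetic biopsies, to find out whether the cells keep a miRNA difference in culture. Total counts were 123379 to 207235 per diabetic sample and 96353 to 174577 per non-diabetic sample, of which miRNA probes held 67379 to 129800 and 52057 to 102917. Of 800 miRNA probes, 92 exceeded the background of the negative controls in at least 1 sample, 65 did so in at least 4 samples and were tested, and 48 did so in all 8. The other 708 probes were not detectable above background in any sample. Among them, 6 had a count of exactly 1 in all 8 samples, a possible floor taken up below, so their level is not known.

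The cultures shared a compact fibroblast profile. The 10 most abundant miRNAs of each sample held 57.2% to 68.9% of its miRNA counts. miR-125b-5p, a regulator of proliferation and differentiation, had the highest level, with 23784 ± 13324 scaled counts in diabetic and 20497 ± 4045 in non-diabetic fibroblasts (mean ± SD, n = 4 each). The let-7 family, which represses growth-promoting genes such as RAS, followed with let-7a-5p at 13500 ± 11525 against 9874 ± 1753 and let-7b-5p at 9620 ± 6244 against 7579 ± 752 (SD, n = 4). let-7g-5p was also among the 10, at 2074 ± 1227 against 1681 ± 374 scaled counts. miR-29b-3p and miR-29a-3p, which repress collagen mRNAs, reached 5467 ± 424 and 2454 ± 1263 scaled counts in diabetic and 6199 ± 2543 and 2569 ± 1006 in non-diabetic fibroblasts. miR-100-5p, miR-23a-3p, miR-221-3p and the probe shared by miR-199a-3p and miR-199b-3p completed the 10, with group means between 2628 and 5122 scaled counts. The group ranges of all 10 overlapped. The marker probes fixed beforehand for other cells were not detectable, and cells without such a probe were not assessed. None of 9 keratinocyte and epithelial, 1 endothelial, 7 blood cell, 7 striated muscle and 6 neural and melanocyte probes exceeded background in any sample. The same held for the 42 probes of the 19q13 placental cluster.

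**Figure D1:**
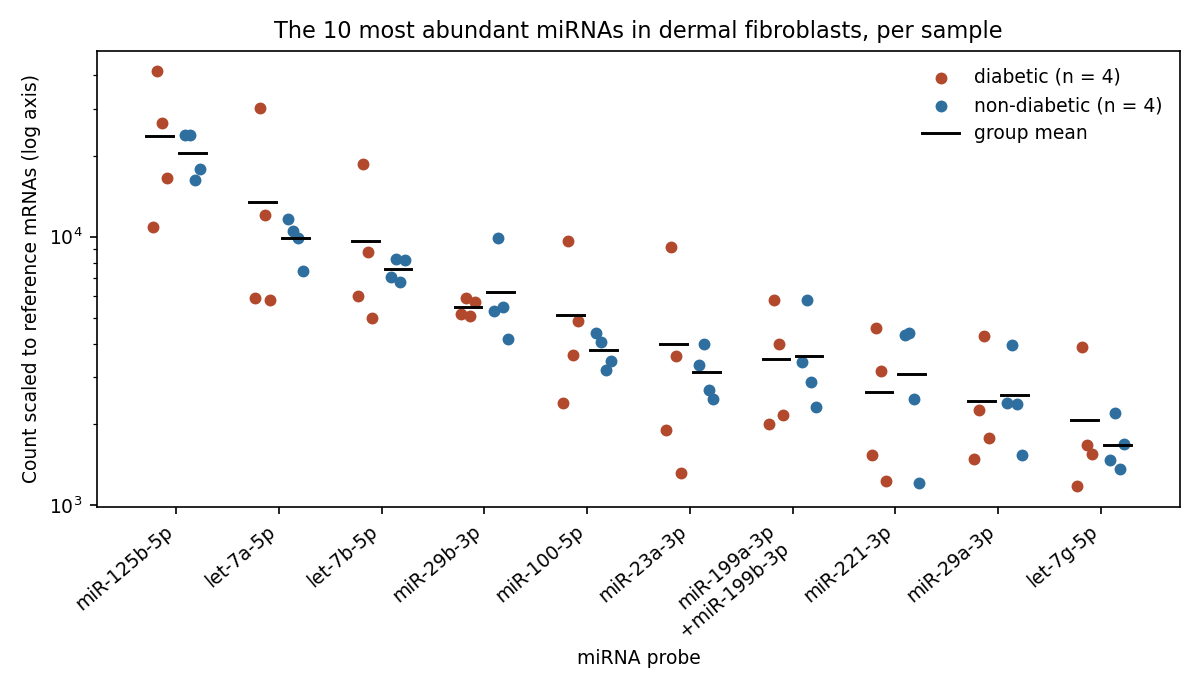
Scaled counts (log axis) of the 10 most abundant miRNAs in each diabetic and non-diabetic sample (n = 4 each), with the group mean as a black line. The points of both groups overlap for every miRNA, and miR-125b-5p is highest in both groups.

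No miRNA differed between diabetic and non-diabetic fibroblasts past the threshold. edgeR called 0 of 65 tested miRNAs (smallest adjusted p = 0.992), and 0 had an unadjusted p under 0.05. DESeq2 called 0 with its own size factors, where 3 had an unadjusted p under 0.05, and 0 with reference mRNA scaling, where 0 did. limma-voom called 0, with 0 at an unadjusted p under 0.05. The fitted log2 fold change, diabetic minus non-diabetic, was above 0 for 44 miRNAs and below 0 for 21, against 30 and 35 under TMM scaling and 54 and 11 under positive control scaling. Positive control scaling moved the median of all 65 miRNAs from 0.08 to 0.23.

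The values with the smallest unadjusted p were as follows, none past the threshold. miR-23b-3p had a log2 fold change of 0.88 (SE 0.70, edgeR unadjusted p = 0.208), with 448 ± 468 scaled counts in diabetic and 242 ± 75.4 in non-diabetic samples (SD, n = 4). The value was 0.43 (SE 0.29) under TMM scaling. Diabetic replicate 2 had 1127 scaled counts against 113 to 385 in the other diabetic samples, and without it the fold change under reference mRNA scaling fell below 0. miR-181a-5p, which tunes immune cell signalling, had a log2 fold change of 0.83 (SE 0.71), and 0.56 (SE 0.26) under TMM scaling. For miR-145-5p, which promotes a contractile cell state, the value was 0.55 (SE 0.58), and it changed sign to -0.02 under TMM scaling. In the other direction miR-4454, whose sequence resembles a transfer RNA, had a log2 fold change of -1.02 (SE 0.58, edgeR unadjusted p = 0.0798), with 1027 ± 588 against 2087 ± 1878 scaled counts. The value was -0.64 (SE 0.96) under TMM scaling and -0.39 under positive control scaling. miR-503, a cell cycle repressor expressed together with miR-424, had -0.47 (SE 0.67), and -0.56 (SE 0.26, edgeR unadjusted p = 0.0489, adjusted p = 0.994) under TMM scaling. miR-218-5p and miR-720 had -0.53 and -0.47, and both changed sign under positive control scaling (0.23 and 0.08). Of the 33 named miRNAs, 22 kept their sign under all 5 other scalings, and 11 changed it under at least 1.

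Fold changes of moderate size remained open under reference mRNA scaling, where the 95% interval lay within 2-fold in either direction for 0 of 65 miRNAs and within 4-fold for 62. Under TMM scaling it lay within 2-fold for 52 of 65.

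**Figure D2:**
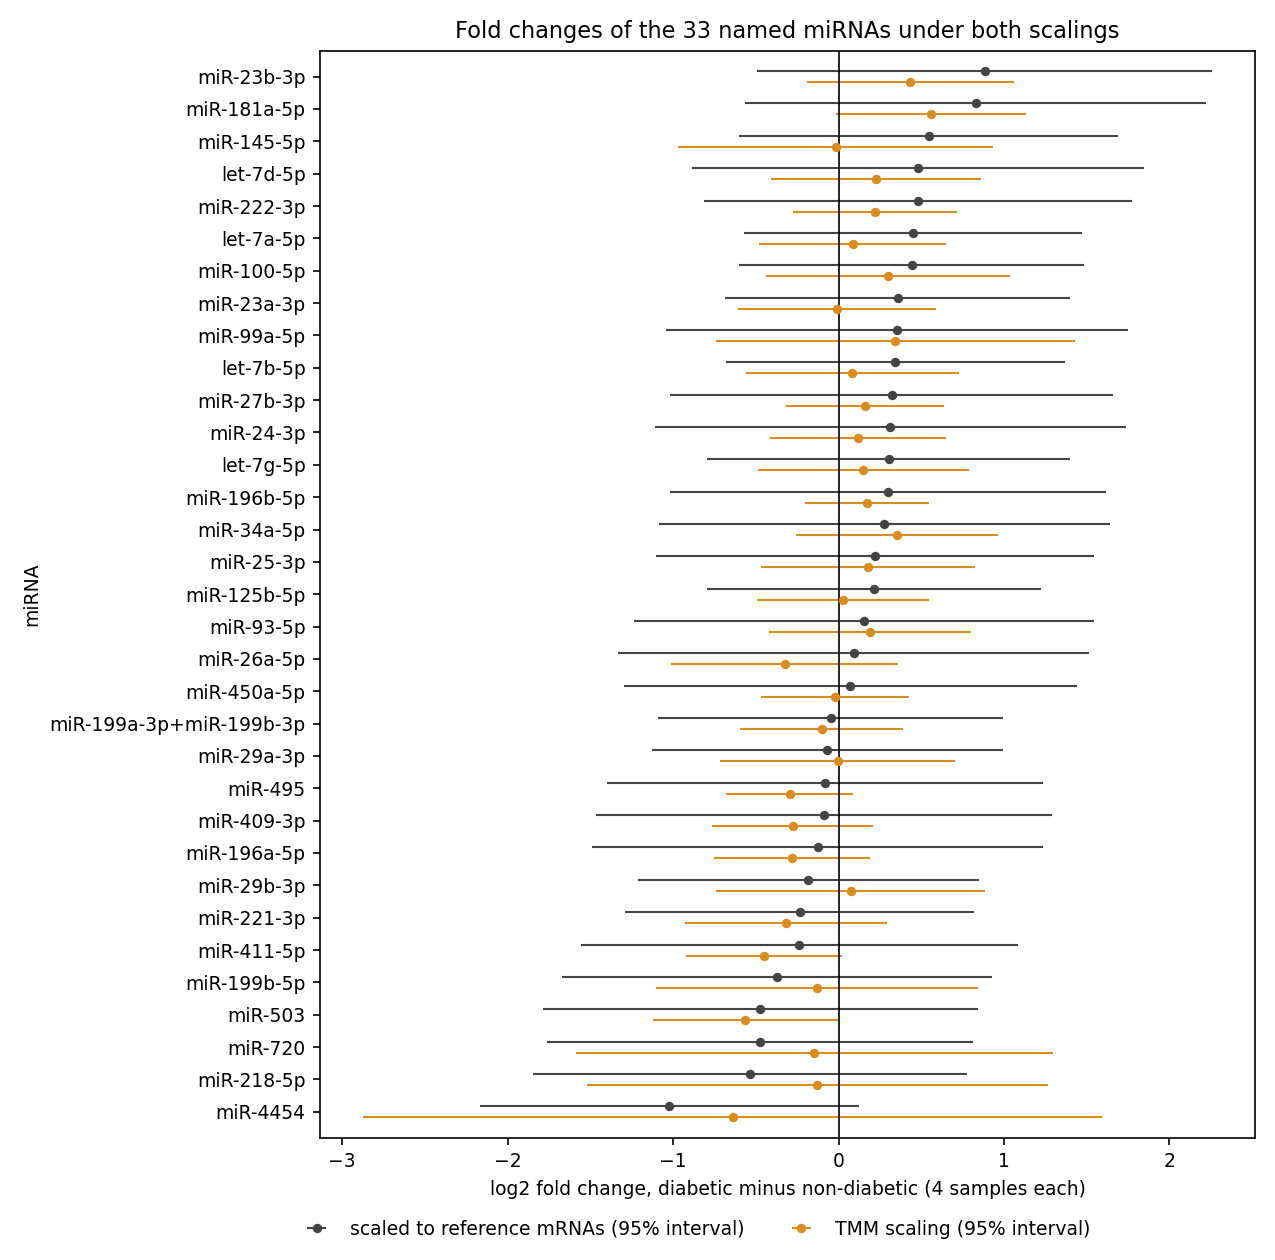
log2 fold change, diabetic minus non-diabetic (x axis), of the 33 named miRNAs with 95% intervals, from 4 samples per group, scaled to reference mRNAs (grey) or by TMM (orange). Intervals are narrower under TMM scaling for most miRNAs, and the TMM interval of miR-503 lies just below 0 before adjustment.

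Functional groups and genomic clusters were compared next. For each list, 0 members passed over all tested miRNAs and 0 passed when adjusted over the list alone. All 9 tested let-7 family members had fitted values above 0 (median log2 fold change 0.34), but 8 of 9 did under TMM scaling, where the median was 0.07. let-7d-5p had 0.48 (SE 0.70) and let-7a-5p 0.45 (SE 0.52). The 4 tested members of the miR-23/27/24 clusters had a median of 0.34, with miR-23a-3p at 0.36 (SE 0.53), which changed sign to -0.01 under TMM scaling. The skin wound healing list had a median of 0.27 over 8 tested members, among them miR-100-5p at 0.44 (SE 0.53) and miR-99a-5p at 0.35 (SE 0.71), and of 0.10 under TMM scaling. The inflammatory response list had 4 tested members with a median of 0.35, among them miR-222-3p at 0.48 (SE 0.66), and of 0.12 under TMM scaling. The sign of these 4 medians rested on 1 culture under reference mRNA scaling. Without diabetic replicate 2 the medians were -0.22 for the let-7 family (8 of 9 below 0), -0.18 for the miR-23/27/24 clusters, -0.21 for skin wound healing and -0.16 for the inflammatory response. All tested members of the last 3 were below 0. So were 62 of all 65 tested miRNAs (median -0.38), so the whole panel moved without that sample. Relative to the other miRNAs, camera with an estimated correlation still placed all 4 lists higher without it (adjusted p = 0.949 for each).

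The pro-fibrotic, anti-fibrotic and high glucose and diabetic tissue lists had members on both sides of 0 under reference mRNA and TMM scaling. Most were above 0 under positive control scaling: 6 of 7 pro-fibrotic (median 0.15), 4 of 4 anti-fibrotic (median 0.27) and 8 of 10 high glucose and diabetic tissue members (median 0.33). That scaling put 54 of all 65 tested miRNAs above 0 (median 0.23), so these counts are not particular to the lists. Of 7 tested pro-fibrotic miRNAs, 4 had values above 0 and 3 below (median 0.04), against 2 and 5 under TMM scaling. miR-199b-5p of this list had -0.37 (SE 0.66), and 0.10 under positive control scaling. The 4 tested anti-fibrotic miRNAs had a median of 0.01 and 0.03 under TMM scaling, with miR-29b-3p at -0.18 (SE 0.53), which changed sign to 0.07 under TMM scaling, and miR-24-3p at 0.31 (SE 0.72). The miR-29 family, with 2 tested members, had a median of -0.12, and 0.03 under TMM scaling. The high glucose and diabetic tissue list had 5 of 10 tested members on each side of 0 (median -0.02, and 0.05 under TMM scaling). For miR-27b-3p of that list the value was 0.32 (SE 0.68). The p53 response and senescence list had a median of 0.16 over 4 tested members, and -0.14 under TMM scaling; miR-34a-5p, a direct target of p53, had 0.28 (SE 0.69). The last 3 groups had 2 tested members each. In the miR-17-92 cluster and its paralogs, miR-25-3p and miR-93-5p had 0.22 and 0.15. miR-196b-5p and miR-196a-5p, which lie in the HOX gene clusters that encode position along the body, had 0.30 and -0.13. In the cluster of miR-424 and miR-503, miR-450a-5p had 0.07, and -0.02 under TMM scaling.

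Of the 9 lists large enough for a test, camera called 0 at the preset correlation, 3 had an unadjusted p under 0.05, and fry and camera with an estimated correlation called 0. The smallest adjusted p belonged to the imprinted 14q32 cluster, a large group of miRNAs expressed from the maternal chromosome (camera adjusted p = 0.0777, and adjusted p = 0.826 with an estimated correlation). Of its 9 tested members, 6 had values below 0 and 3 above (median log2 fold change -0.04), with miR-411-5p at -0.24 (SE 0.67) and miR-409-3p at -0.09 (SE 0.70), which was 0.03 under positive control scaling. Under TMM scaling all 9 were below 0 (median -0.28) and camera called the cluster (adjusted p = 0.000472), a call lost with an estimated correlation (adjusted p = 0.351). fry, which tests the members against no change and not against the other miRNAs, gave adjusted p = 0.787. The let-7 family and the miR-23/27/24 clusters both had a camera adjusted p of 0.102. Single samples changed these calls: without diabetic replicate 2, non-diabetic replicate 2 or non-diabetic replicate 3 the 14q32 cluster had adjusted p = 0.000165, 0.0149 and 0.0017 at the preset correlation, and 0.949, 0.942 and 0.928 with an estimated one. Without non-diabetic replicate 2 all 9 members were above 0 (median 0.14), as were 59 of all 65 tested miRNAs, so that this call was relative to the other miRNAs. Without diabetic replicate 2 all 9 were below 0, but so were 62 of the 65, so that call was relative as well. Without non-diabetic replicate 3 all 9 were below 0, against 31 of the 65. Without diabetic replicate 4 the let-7 family and the miR-23/27/24 clusters had adjusted p = 0.0217, and without non-diabetic replicate 3 the let-7 family had adjusted p = 0.0192; with an estimated correlation these were 0.852 and 0.928.

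The number of detected miRNAs did not differ past the threshold. Diabetic fibroblasts had 64.8 ± 14.7 miRNA probes above background and non-diabetic fibroblasts 66.3 ± 10.2 (SD, n = 4, exact permutation p = 0.914). The 5 reference mRNAs varied more between samples than the positive controls, with a geometric mean count of 992 to 3726 (3.76-fold) against 816 to 1498 (1.84-fold). Mean raw counts in diabetic and non-diabetic samples were 2222 ± 1610 and 1443 ± 547 for ACTB, 2804 ± 2157 and 1957 ± 1369 for B2M, and 2101 ± 1404 and 1379 ± 339 for GAPDH (SD, n = 4). For RPL19 they were 1937 ± 1108 and 1359 ± 647, and for RPLP0 2721 ± 1648 and 2012 ± 995. Scaled to the positive controls these mRNAs had log2 differences, diabetic minus non-diabetic, of 0.19 to 0.29, against -0.05 to 0.05 under TMM scaling. The log2 ratio of miRNA to reference mRNA signal was 5.46 ± 0.80 in diabetic and 5.43 ± 0.37 in non-diabetic fibroblasts (SD, n = 4, exact permutation p = 0.914), and this ratio spanned 3.52-fold across samples. Its difference of 0.03 became -0.32 without diabetic replicate 2.

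**Figure D3:**
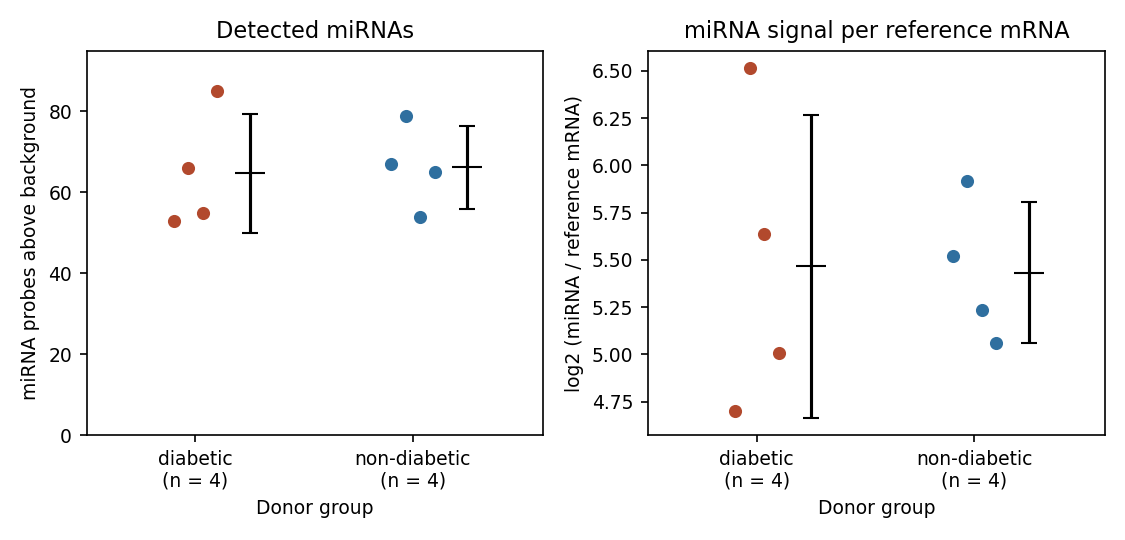
Left, miRNA probes above background per sample; right, log2 ratio of summed miRNA counts to the reference mRNA geometric mean (axis not starting at 0). Points are samples (n = 4 per group) and bars the mean ± SD; the groups overlap in both panels, and the ratio spreads from 4.70 to 6.51 in diabetic samples.

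The authors' deposited table lists 22 miRNAs with a fold change over 2-fold, 11 higher and 11 lower in diabetic fibroblasts. The authors' deposited table gives -10.1 for miR-503, -3.87 for miR-26a-5p, 2.92 for miR-93-5p, 2.75 for miR-196b-5p and -2.70 for miR-495, the 5 largest among tested miRNAs. On raw counts with the main scaling, edgeR gave fold changes of 0.72, 1.07, 1.11, 1.23 and 0.95 for the same miRNAs. These are unsigned ratios of fitted group levels, not of geometric means. As signed ratios of geometric means, the same scaled counts gave -1.42, -1.28, 1.15, 1.15 and -1.21, each in the deposited direction. The edgeR value of miR-26a-5p changed sign on the log2 scale from 0.09 to -0.32 under TMM scaling. Of the 22 miRNAs, 19 were at or below background in at least 1 sample, 16 in at least 3, and 10 were not tested. From the same counts under the main scaling, with nothing subtracted, 2 of 22 exceeded 2-fold. The median size was 1.26-fold, against 2.67-fold in the authors' deposited table. The main scaling is not the authors' factor per sample, so the scaling changed along with the subtraction. Counts with nothing subtracted keep the background, which draws a fold change toward 1. With the mean of the negative controls subtracted, a test chosen after seeing the data, 4 of 22 exceeded 2-fold in the deposited direction. The median size in either direction was 1.45-fold. Of the 4, 2 had at least 1 sample at the floor of 1, miR-21-5p and miR-218-5p. In the direction opposite to the deposited one, miR-204-5p was 3.30-fold higher and miR-376c 2.59-fold lower in diabetic fibroblasts, both also with samples at the floor. The 2 with nothing subtracted, miR-21-5p and miR-143-3p, are named after their values were seen and were not tested, with 3 samples and 1 sample above background. The authors' deposited table lists 711 miRNAs at -1.02, of which 708 exceeded background in no sample, and for these 708 the value stands for no measured level.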

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

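Among 84 groups of 4 values examined, 5 held a sample far from the other 3, against about 4.2 that chance gives at 1 in 20. All 5 are counts scaled to the reference mRNAs, and each is given with the gap to its nearest neighbour as a share of the group's range. In diabetic fibroblasts, miR-181a-5p stood at 627 scaled counts in replicate 2, with the nearest sample at 147 (share 0.917). miR-145-5p was at 3150 in the same sample and 708 in the nearest (share 0.895), and miR-34a-5p at 755 and 366 (share 0.831). This sample had the lowest reference mRNA geometric mean of all 8, 992 counts. Its scale factor relative to the mean of the samples was 0.51 from the reference mRNAs and 1.24 from TMM. Before scaling it had 322 counts of miR-181a-5p against 283 in diabetic replicate 4, and 1618 of miR-145-5p against 1059. For miR-34a-5p it had 388, below the 589 of diabetic replicate 1. These 3 flags thus depend on the reference mRNA scaling. In non-diabetic fibroblasts, miR-199b-5p stood at 1998 in replicate 2 and 488 in the nearest sample (share 0.907), and miR-99a-5p at 422 and 134 (share 0.847).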

How the results depend on the processing

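Fits within lanes 1 to 6 (1 non-diabetic sample) or 7 to 12 alone, the lane terms under TMM scaling, TMM scaling with each sample left out, the authors' recovered factors, TMM scaling without miR-4454, miR-720 and miR-1260a, TMM scaling with fry or with the mean negative control subtracted, and an estimated correlation in every alternative were chosen after seeing the data. edgeR, DESeq2 or limma called 0 miRNAs in all 40 alternatives, 25 planned and 15 added, with at most 3 at an unadjusted p under 0.05. The smallest adjusted p was 0.883 to 1.00 over the planned ones and 0.12 over all, for lanes 7 to 12 alone. Without diabetic replicate 2, 3 miRNAs had values above 0 and 62 below; without non-diabetic replicate 2, 59 and 6. With the lane as a covariate 17 were above and 48 below. For the named miRNAs, 1110 of 1309 alternative values kept their sign and 199 changed it, 0 of them called; miR-25-3p alone kept its sign throughout.

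With an estimated correlation, camera called 0 lists in the main fit and in all 36 alternatives run (smallest adjusted p = 0.188), so the calls that follow hold at the preset correlation of 0.01 only. The count of shifted lists, 0, became 1 under TMM, positive control, top 100 miRNA and total miRNA scaling, with the highest negative control as background, with the deposited signal at pseudocount 1, with the series matrix, with the mean negative control subtracted, and with the lane as a block or a covariate. It was also 1 with either lane term or with the mean negative control subtracted under TMM scaling and under TMM scaling without the 3 transfer RNA-like probes. In each case the list was the 14q32 cluster, under positive control scaling with 4 of 9 members below 0, and the cause was not tested. Leaving out single samples gave 0 to 2 lists, and 0 to 3 under TMM scaling: 0 without diabetic replicate 3 or non-diabetic replicate 4, 1 in 4 cases, and 3 without diabetic replicate 4 or non-diabetic replicate 1. Over the alternatives fixed before the data were examined, the camera adjusted p of the cluster at the preset correlation ran from 1.5e-05 to 0.747.

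The difference in the miRNA to reference mRNA ratio, 0.03, was -0.024 with the geometric mean of the miRNAs and -0.32 to 0.29 with single samples left out. With the positive controls as denominator in place of the reference mRNAs it was 0.26. The difference in detected miRNAs, -1.50, was 2.75 above the mean of the negative controls, 1.00 above their mean plus 3 SD, and -8.25 to 2.75 with single samples left out. No exact p in these alternatives was under 0.05, and the cause was not tested. Spike-in scaling was not run, because all 5 spike-ins were below background (highest count 36). No paired analysis was possible because the groups share no sample numbers.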

Other observations

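The tests on the deposited fold changes and on values of 1, the correlations, and the counts of splits for called miRNAs and lists were chosen or read after the results were seen; those on the 14q32 cluster were set out after the cluster was seen to be lower under TMM scaling, but before their own values, except that the lane fits with samples left out and the fits with the mean of the negative controls subtracted were added later.

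Some miRNAs varied widely between cultures. Under TMM scaling the median within-group SD of a tested miRNA was 0.36 on the log2 scale, and 6 of 65 miRNAs spanned more than 4-fold over the 8 samples. miR-4454 spanned 23.1-fold, miR-218-5p 6.49-fold, miR-720 5.93-fold and miR-99a-5p 5.25-fold. miR-4454 and miR-720, both of transfer RNA-like sequence, varied together over the 8 samples relative to the positive controls (Pearson's r = 0.978, exact permutation p = 0.000149, adjusted over 6 relations p = 0.000893; Spearman's rho = 0.952, exact permutation p = 0.00114, adjusted p = 0.00685). Without the 2 samples farthest from the median r was 0.957. miR-1260a had r = 0.783 with miR-4454 (exact permutation p = 0.0269, adjusted p = 0.0404; rho = 0.738, exact permutation p = 0.0458, adjusted p = 0.0917, not past the threshold), and 0.715 without those 2. For miR-720 and miR-1260a r was 0.828 (exact permutation p = 0.0162, adjusted p = 0.0324; rho = 0.69, exact permutation p = 0.0694, adjusted p = 0.104), and 0.787 without the 2 farthest samples. Of the other 3 relations, reference mRNAs had r = 0.852 with miR-29b-3p (exact permutation p = 0.00707, adjusted p = 0.0212; rho = 0.833, exact permutation p = 0.0154, adjusted p = 0.0461), which fell to 0.507 without the 2 farthest samples and so rests on them, 0.535 with miR-125b-5p and 0.292 with miR-4454 (exact permutation p = 0.172 and 0.474, adjusted p = 0.206 and 0.474; rho = 0.238 and 0.357, exact permutation p = 0.582 and 0.389, adjusted p = 0.582 and 0.467; r = 0.246 and -0.08 without those 2). Lanes 1 to 6 hold 3 samples and lanes 7 to 12 hold 5, fewer than the 6 taken here as the least for a correlation. With both variables centred within these lane groups, r over the 8 samples was 0.978 for miR-4454 and miR-720 (exact permutation p = 0.00278, adjusted p = 0.0167) and 0.783 for miR-4454 and miR-1260a (exact permutation p = 0.0528, adjusted p = 0.0792), and the adjusted exact permutation p of the other 4 relations was 0.0792 to 0.487. These pairs were chosen after their values were seen.

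For the 0 miRNAs and 0 lists called between the groups by edgeR and camera, all 35 of 35 splits of the 8 samples into 4 and 4 gave at least as many, which a count of 0 fixes in advance, so these counts say nothing about chance; the highest other split called 56 miRNAs, and the highest for lists was 2. The split with 56 set diabetic replicates 1 and 4 and non-diabetic replicates 3 and 4, the 4 samples with the lowest miRNA to reference mRNA ratios, against the rest, and called 0 under TMM scaling. It points to a structure of the samples in that ratio only, which the main scaling carries into every miRNA, so the 56 say nothing beyond it.

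The 9 tested miRNAs of the 14q32 cluster were all lower in diabetic fibroblasts under TMM scaling, with a median log2 fold change of -0.28 (0.82-fold), and of -0.37 to -0.17 with each sample left out. Their mean centred log2 level was -0.15 ± 0.23 in diabetic and 0.15 ± 0.20 in non-diabetic samples (SD, n = 4, exact permutation p = 0.114). Of 35 splits, 4, the real one included, gave a median shift at least as large, up to 0.38 in size against 0.29, so chance cannot be excluded. The cluster's median was -0.34 with the lane block and -0.43 with the lane number, and -0.46 to -0.22 over both terms with each sample left out. The shift thus did not shrink in either fit to all samples. Within lanes 1 to 6 and within lanes 7 to 12, however, every diabetic sample ran in a lower lane than every non-diabetic one. The block and the fits within lane groups therefore cannot separate lane from group. The lane number fit assumes a linear trend, so the cartridge lane stays open. Under reference mRNA scaling the cluster's median minus that of all tested miRNAs was -0.31 within lanes 7 to 12 (camera adjusted p = 0.20), where all 9 members were below 0 (median -0.66). Within lanes 1 to 6 it was -0.27, but 0 of 9 were below 0 (median 0.75), and 1 non-diabetic sample leaves it without weight. Background counts of dim probes stay open. The 21 other tested miRNAs of the same range of mean counts (113 to 293) had a median of -0.036, above the cluster by more than 0.14. Of 10000 random draws of 9 of them, 100% lay above the cluster's median. Only 92.2% did so by that much, short of the 95% set beforehand. With the mean of the negative controls subtracted the TMM median was -0.37 (9 of 9 lower, camera adjusted p = 0.000959, and adjusted p = 0.4 with an estimated correlation), but -0.47 to -0.12 with each sample left out. At the preset correlation that call was lost without diabetic replicate 1, diabetic replicate 3 or non-diabetic replicate 4 (camera adjusted p = 0.0613, 0.319 and 0.135). A difference with diabetes stays open.

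Of the 22 deposited fold changes over 2-fold, 4 stayed over 2-fold in the same direction when only the mean of the negative controls was subtracted. The main scaling was used there in place of the authors' factors. An effect of background subtraction and the floor of 1 is a candidate explanation, which this count cannot decide. The 22 were picked for exceeding 2-fold on the deposited signal, so the count could only fall. The mean-subtracted values also kept a floor of 1, so the floor itself was not tested. A group difference of the deposited size cannot be told apart from an effect of background subtraction for the 12 tested miRNAs, because the intervals are wide. With the mean subtracted the 95% interval excluded the deposited value for 1 of 12, miR-503. On the deposited signal limma called 0 of the 12, and with a pseudocount of 20 miR-503 had a log2 fold change of -1.31 (unadjusted p = 0.036, adjusted p = 0.982). The other 10 were not tested, and a difference stays open for them as well.

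miR-21-5p, among the best known fibroblast miRNAs and chosen here after its values were seen, had a count of exactly 1 in 5 samples and of 775 to 1266 in the other 3. The table of raw counts holds no 0, and 10 probes were at 1 in at least 4 samples, holding 67 of its 94 values of 1, while undetected probes had a median of 12. A floor of 1 set for some probes before deposit is a candidate explanation. The RNA amount in the assay goes against the total miRNA counts, which differed by 2.49-fold. Diabetes of the donor cannot be told apart from other causes, with 2 of 4 diabetic and 1 of 4 non-diabetic samples above background (Fisher's exact test, two-sided, p = 1).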
